A study of Homo sapiens
Mus musculus with 2 samples.

How the data were processed

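Single cells of the colonic epithelium of 1 wild-type C57Bl6 mouse were profiled as 2 libraries, called replicates 1 and 2. Per the labels' protocols, the epithelium was taken apart with EDTA and with collagenase and DNase, viable cells were enriched on magnetic columns, and cells of the human leukaemia line K562 were added. The mixture was encapsulated with inDrop, a droplet method that gives each cell a barcode, and the RNA was amplified by CEL-Seq and sequenced on a NextSeq500. Per the design text of the series, the libraries hold different cells of the same animal in a single sequencing run. They therefore form 1 group, and no comparison between conditions was possible. Every p-value covers only how class differences vary between 2 libraries of 1 animal, a spread that may be technical.

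The deposited tables hold whole-number counts of unique molecular identifiers (UMIs, which mark single captured molecules) per gene and barcode, without normalization. The builds GRCh38 and GRCm38 are named per the submitters' processing notes. The aligner, the annotation, the strand of counting and the filter that chose the barcodes are not given in the sources used here. Counts of neighbouring, antisense and near-identical genes are therefore uncertain. The tables of both libraries list the same 25504 genes, of which 1259 had no UMI. No barcode of one library has the same counts over all genes as a barcode of the other. Replicate 1 holds 1738 barcodes with 8602490 UMIs and replicate 2 holds 664 barcodes with 3951918 UMIs. The lowest total of a barcode was 1001 UMIs in replicate 1 and 1002 in replicate 2. No gene symbol is written in capitals only, and the K562 cells, their share and mixed-species barcodes were not analysed here.

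Barcodes with at least 500 UMIs and at least 250 genes were kept, which removed 0 barcodes. Doublets were scored from 2 simulated pairs per barcode and the share of simulated pairs among 50 neighbours, and the 5% of barcodes with the highest score were left out of each library, 87 in replicate 1 and 33 in replicate 2. Genes were divided once by the md5 sum of their symbol into 12615 clustering genes and 12889 readout genes. Cell type markers were always clustering genes, and members of the gene lists and mitochondrially encoded genes were always readout genes. No gene tested between classes had therefore itself helped to define them. Related and co-regulated genes can fall on both sides, as Gsdmc and Clca4b among clustering and Gsdmc4 and Clca4a among readout genes do. The tests are thus not independent of the clustering. Counts of clustering genes were scaled to 10000 per cell and log-transformed, the 1500 most variable genes were reduced to 30 principal components, and a shared nearest neighbour graph of 15 neighbours was divided by the Leiden method at resolution 1. Both libraries were clustered together without integration. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, igraph 0.11.9 and leidenalg 0.10.2 was used.

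Clusters were named from marker lists for epithelial, immune, stromal and red cells. A class score was the mean over its markers of the log2 level, with 10 CPM (UMIs per 1e6 UMIs) added, relative to the mean over clusters. A cluster took the class with the highest score relative to that class's best cluster, given a score of at least 0.75 and at least 3 markers with a UMI in 10% of its cells. It stayed unnamed where none of the markers of that class was among its 15 leading genes or where more markers of another class were. Leading genes were the clustering genes with the largest fold over all other cells after adding 20 CPM, among those with at least 20 UMIs and a UMI in 10% of the cells. Deep crypt secretory-like cells also needed Reg4 among the leading genes. This condition decided the name of 1 goblet-like cluster, led by Sval1, Scin and Slpi. Its deep crypt secretory score of 3.13 was above the 2.98 of the cluster that took that name, and it held Reg4 in 81.4% of its cells, so that for this cluster the line between these 2 classes rests on Reg4 leading. A cluster with the highest stem marker score that cycling markers led too was called stem/cycling. The markers, the gene lists, the tests and most alternatives were fixed before the data were examined. The scoring rule was settled after the clusters had been seen, in 3 versions, and before any test between classes was run.

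UMIs were summed per library and class for every epithelial class with at least 10 cells in each library, giving 10 sums of 254574 to 2860407 UMIs. The 8182 readout genes with at least 20 UMIs over all sums were tested with edgeR 4.0.16 (glmQLFit and glmQLFTest, R 4.3.3) after TMM normalization, with the library as a block. The pairing comes from construction, since all classes were taken from the same libraries. The common dispersion was 0.0109 and the fit had 4 residual degrees of freedom. With so few, the smallest p-values rest largely on dispersion pooled over genes. Each class was compared with the mean of the other 4 classes, and goblet-like with colonocyte-like cells. Adjusted p-values are by the Benjamini-Hochberg method at a threshold of 0.05. A fitted fold is a difference of mean log2 levels, so that every other class has the same weight. A class may lie above that mean and still below the arithmetic mean of the other classes where one of them, often colonocyte-like cells, holds a far higher level. The standard error is the log2 fold change divided by the square root of the F statistic. CPM are over all UMIs of a sum.

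The named genes were chosen by a fixed rule among readout genes past the threshold with the same sign in each library alone and at least 20 UMIs in the higher class. They were the 10 largest positive and 6 largest negative log2 fold changes of a class, the 5 largest each way of a pair, and up to 6 members per list by absolute change, of which at most 4 per list are described. Predicted, ribosomal protein and mitochondrially encoded genes were counted and not named outside their list. Where the lower side held 0 UMIs over both libraries, the fold is given as a lower bound against a floor of 3 counts over both libraries pooled. Where it held 1 to 3 UMIs, or where any of the other classes held 0, the pooled ratio with its exact 95% interval is given. Both compare a class with the UMIs of all other classes pooled, in which large classes weigh most, so that they are no bounds of the fitted contrast. Such intervals, the Clopper-Pearson intervals of shares and the Poisson intervals of counts cover counting error only.

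There were 21 gene lists. They cover ion, water and short-chain fatty acid transport, fatty acid oxidation and ketogenesis, brush border, secretory pathway and unfolded protein response, mucin O-glycosylation and goblet secretion, antimicrobial defence, taste transduction and eicosanoid synthesis, immune-type signalling and cytoskeleton, and neuroendocrine secretion. Further lists hold enteroendocrine, secretory and tuft, and absorptive transcription factors, DNA replication, mitosis, Wnt target and crypt-base genes, the Notch pathway, ribosome biogenesis, immediate early and dissociation response genes, MHC class II and interferon response genes, mitochondrially encoded genes and ubiquitous reference genes. Lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry (limma 3.58.1, voom weights), adjusted by Benjamini-Hochberg over 105 tests. Fry asks whether the members move on balance in a single direction and does not compare a list with other genes.

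The tests were run on simulated data in which 200 genes had been changed. Of genes changed 4-fold, 83.6% were recovered for colonocyte-like, 75.4% for goblet-like, 72.3% for deep crypt secretory-like, 63.5% for stem/cycling and 58.5% for cycling-like cells, on 7982 to 7996 genes. At 2-fold these shares were 53.1%, 32.8%, 38.7%, 38.5% and 17.2%, and at 1.5-fold 19.7%, 12.3%, 17.9%, 15.2% and 3.08%. For the pairs, 71.9% of genes changed 4-fold were recovered between goblet-like and colonocyte-like cells and 56.3% between deep crypt secretory-like and goblet-like cells. Between 0 and 5.06% of the calls were unchanged genes. A changed list of 20 genes was found in each comparison, and 0 of 20 unchanged lists had a camera p under 0.05 in any comparison. With fry 0 to 2 of 20 did. Only 200 genes were changed, against up to 3336 called in the data, so that these rates need not hold there. Nor do they speak for the preset correlation, at which camera called 66 of 105 lists in the data, against 14 at an estimated one.

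Alternatives were relative log expression size factors, DESeq2 1.42.0, no filter on low counts, at least 50 UMIs per gene, no replicate block, resolutions of 0.5 and 2, the other set of genes for clustering, at most 20% mitochondrially encoded UMIs, no doublet filter, sums thinned to equal depth, each class against all other epithelial cells summed, and each library alone. A minimum of 1000 UMIs per barcode removed nothing. A minimum of 2000 UMIs, the colonocyte-like class without its shallow cluster, the other set of clustering genes for shares, the comparison of deep crypt secretory-like with goblet-like cells and the contrasts between single clusters were added after the data had been seen. Planned comparisons of tuft-like and enteroendocrine-like cells were not run, because too few cells took those names.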

Results

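The 2 libraries of dissociated colonic epithelium from 1 wild-type mouse held 2402 barcodes with 12554408 UMIs. Replicate 1 had 1738 barcodes with a median of 4615.5 UMIs (range 1001 to 17891) and 2020.5 genes. Replicate 2 had 664 barcodes with a median of 4756.5 UMIs (range 1002 to 22505) and 2013 genes. The goblet cell genes Zg16 (2.09% of UMIs in replicate 1 and 1.54% in replicate 2) and Muc2 (1.10% and 0.804%), the mitochondrially encoded mt-Co2 (1.10% and 2.11%) and Lypd8 (1.13% and 0.810%) were among the most abundant transcripts. Mitochondrially encoded genes made up a median of 4.43% of the UMIs of a barcode in replicate 1 and 8.91% in replicate 2.

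Clustering of 1651 and 631 barcodes gave 13 clusters, 11 of which took a name from their markers. Colonocyte-like cells, in 4 clusters, were the largest class, with 34% of the cells of replicate 1 (95% interval 31.8% to 36.4%) and 29.3% of replicate 2 (25.8% to 33.0%). Goblet-like cells made up 17.4% (15.6% to 19.3%) and 10.9% (8.61% to 13.6%). Deep crypt secretory-like cells, led by Reg4, Nov, Txndc5 and Ccl6, made up 17.0% (15.2% to 18.9%) and 12.8% (10.3% to 15.7%). A cluster led by stem and cycling markers together, with Cdca7 and Stmn1, held 10.7% (9.27% to 12.3%) and 7.29% (5.39% to 9.60%). A cycling-like cluster led by Top2a, Ube2c and Hmgb2 held 3.45% (2.63% to 4.45%) and 4.44% (2.97% to 6.35%). Clustered alone, replicate 1 had 10.6% and replicate 2 had 8.08% cycling-like cells, and replicate 2 had no stem/cycling cluster. Tuft-like cells were rare, at 0.545% (0.250% to 1.03%) and 0.317% (0.0384% to 1.14%). A UMI of at least 5 tuft markers was found in 12 cells of replicate 1 and 6 of replicate 2, and 3 and 4 of these cells lay outside the tuft-like cluster. T cell-like cells made up 3.33% (2.52% to 4.31%) and 1.43% (0.654% to 2.69%), and their cluster also held plasma-type cells. Igha led it, and Igkc stood at 27339 CPM in it in replicate 1, with a UMI in 5 of 55 cells. Unnamed cells made up 13.5% (11.9% to 15.3%) and 33.4% (29.8% to 37.3%). No cluster took the enteroendocrine name. Shares are of cells recovered after dissociation and viable-cell enrichment, and their intervals cover counting error only.

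**Figure D1:**
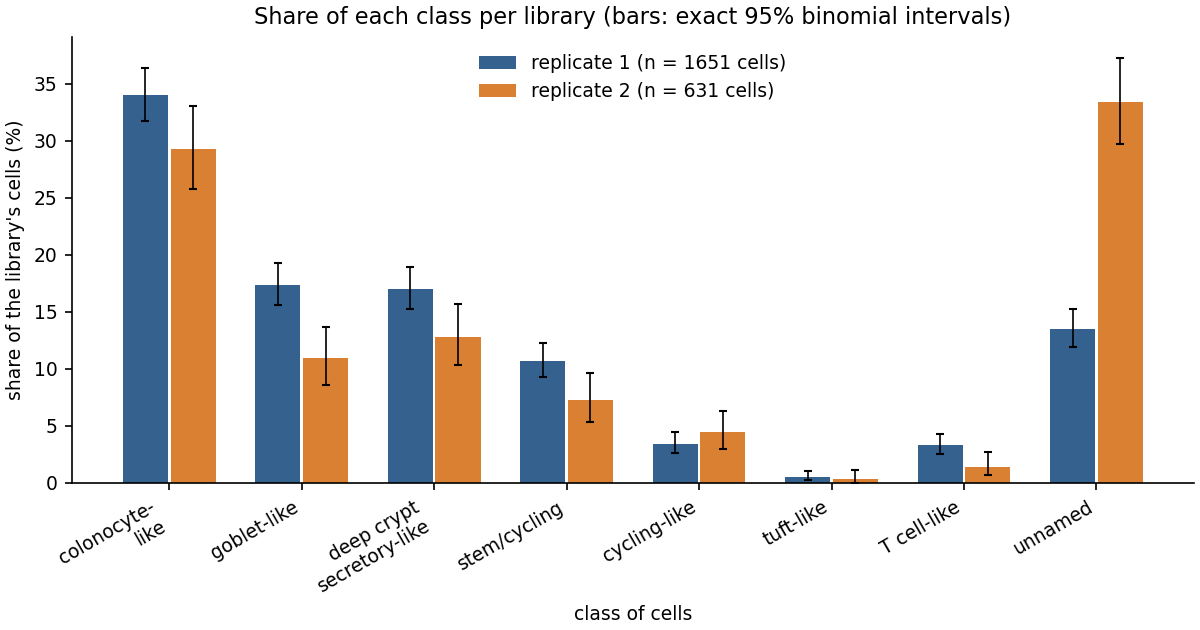
Share of cells per class in each library with exact 95% intervals. Colonocyte-like cells made up 34% of replicate 1 and 29.3% of replicate 2, and unnamed cells 13.5% and 33.4%.

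The stem/cycling cluster held Lgr5 at 23.0 CPM with a UMI in 10.8% of its cells, Ascl2 at 19.0 CPM, Axin2 at 57.6 CPM and Smoc2 at 91.4 CPM. None of these genes was among its leading genes. Its stem score of 1.13 was the highest, against 0.68 in the largest unnamed cluster and 0.63 in the cycling-like cluster. Its cycling score was 2.20, so that a stem identity rests on a narrow lead. Reg4 was found in 83.6% of deep crypt secretory-like cells of replicate 1 and 82.7% of replicate 2, at median depths of 5313 and 7546 UMIs. It was also found in 32.7% and 22.2% of T cell-like cells, which should lack it, at median depths of 1668 and 2138 UMIs. Zg16 stood at 94937 and 88326 CPM in goblet-like cells and at 3760 and 3187 CPM in T cell-like cells. Free RNA in the droplets is a possible source. The T cell-like cluster also had the highest median doublet score of any cluster, 0.58, so that barcodes of mixed cells are not ruled out. One of the 4 colonocyte-like clusters was shallow, with a median of 1709.5 UMIs and 13.4% of UMIs from mitochondrially encoded genes. Mcpt1, a mast cell protease gene, had 494 of its 521 UMIs in 1 cell of the stem/cycling cluster.

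**Figure D2:**
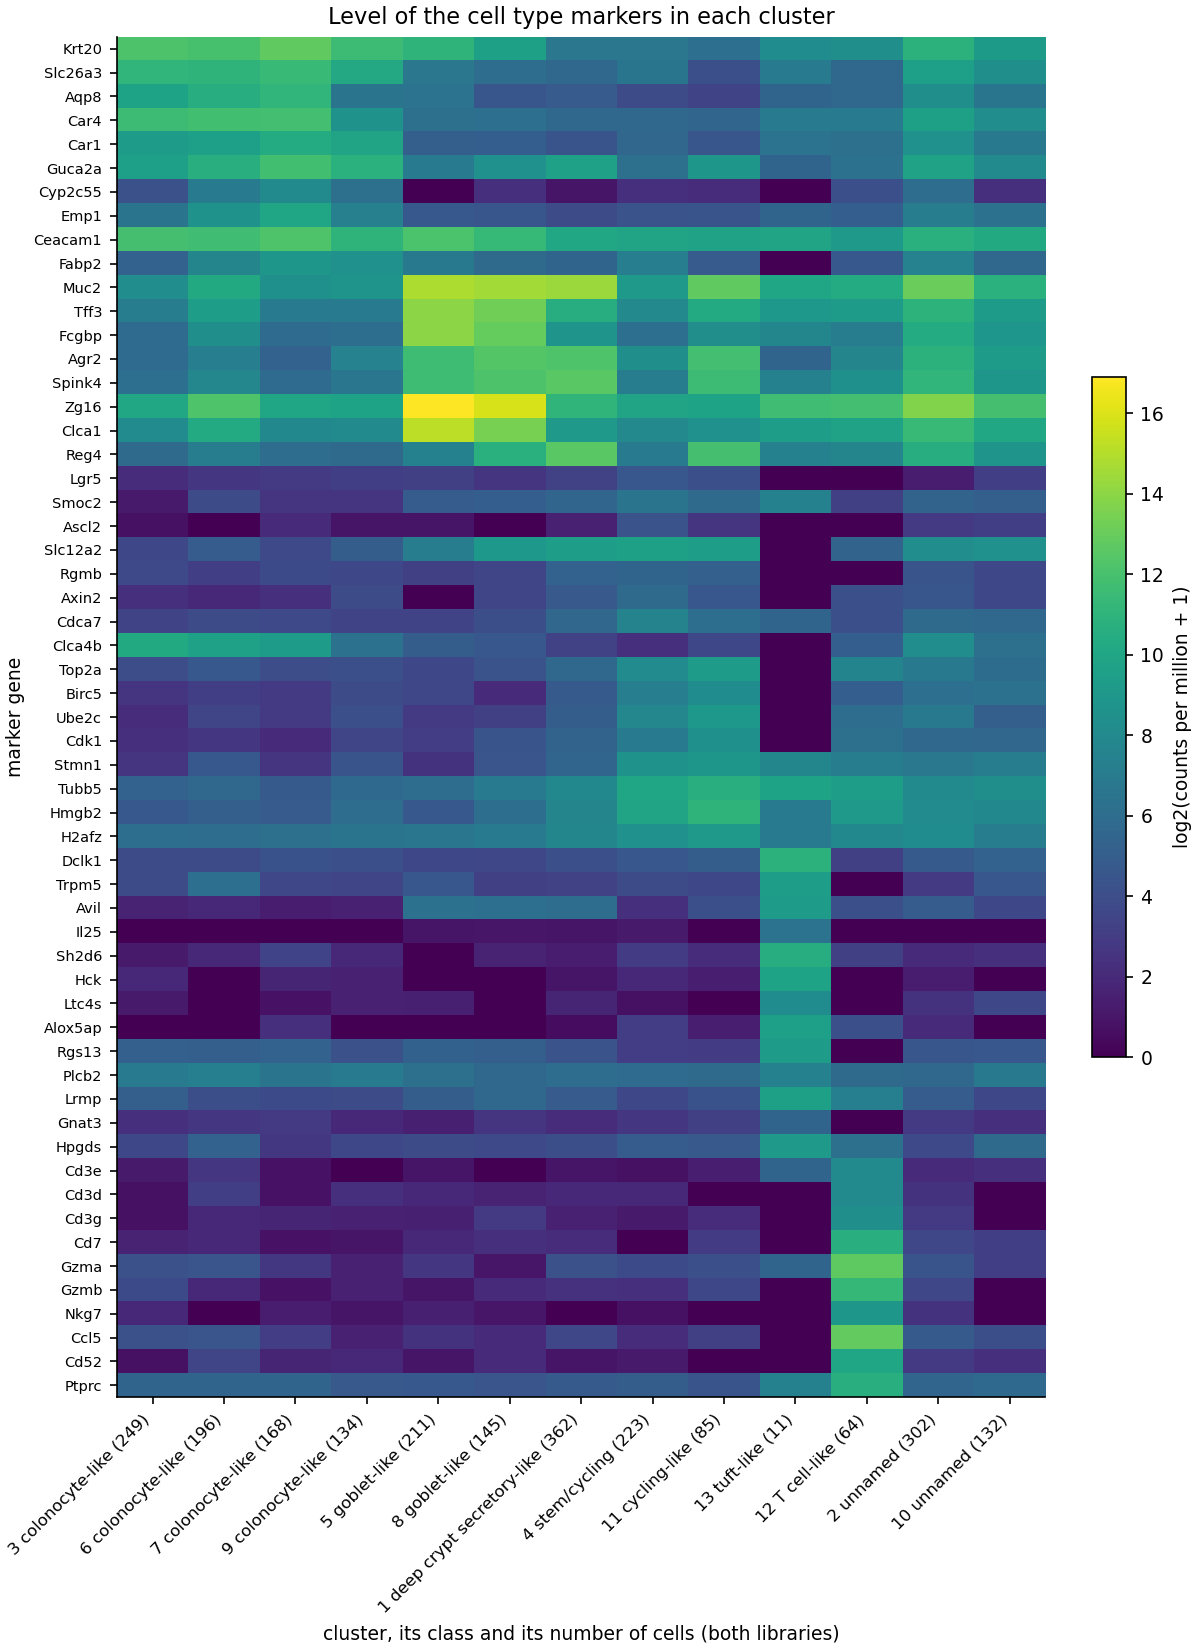
Levels of cell type markers per cluster. Reg4 reached 6310 CPM in deep crypt secretory-like cells of replicate 1 and 67.1 CPM in colonocyte-like cells.

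In colonocyte-like cells Tgm3, a transglutaminase gene, lay above the mean of the other 4 classes by a log2 fold change of 6.09 ± 0.13, and Ly6d by 5.85 ± 0.22 (standard errors; n = 2 libraries here and in every comparison). Ces2c (5.94 ± 0.14), Ceacam20 (5.76 ± 0.17) and the peptide transporter gene Slc15a1 (5.73 ± 0.22) were also higher. Where another class had no UMI, pooled ratios were 33.4 for Clca4a (23.1 to 49.8), 42.2 for the sialyltransferase gene St8sia5 (17.7 to 132), 19.6 for the meprin gene Mep1a (15.6 to 25.0) and 15.7 for Cyp2d9 (8.68 to 31.2). Ces2c, Clca4a and Cyp2d9 have close paralogs whose reads may be among their counts. Slc39a13, a zinc transporter gene, was at least 11.1-fold lower than in the other classes pooled, and in the fitted contrast Ttr lay at -5.38 ± 0.34, the KDEL receptor gene Kdelr3 at -4.77 ± 0.43, the phosphodiesterase gene Pde2a at -4.59 ± 0.30 and the transcription factor gene Spdef at -4.42 ± 0.35. Of 8182 genes, 3336 differed in edgeR's quasi-likelihood test after Benjamini-Hochberg adjustment, 1782 higher and 1554 lower, and 2176 of them by at least 2-fold. Against all other epithelial cells summed the balance turned to 1518 higher and 1820 lower, or 45.5% higher and not 53.4%. With sums thinned to equal depth 1790 genes differed. In the edgeR test with 3336 calls Ly6d had an adjusted p = 5.05e-155 (Benjamini-Hochberg) and Slc39a13 an adjusted p = 4.23e-06.

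Of 21 transport genes tested, 18 were higher and 3 lower in colonocyte-like cells, among them Slc15a1, the bile acid transporter subunit Slc51b (5.50 ± 0.33), the proton pump Atp12a (4.90 ± 0.15) and the sodium-proton exchanger Slc9a2 (4.79 ± 0.16). Camera gave the transport list an adjusted p = 5.43e-19, and 0.0520 with an estimated correlation. Of 16 brush border genes 14 were higher, with Dpep1 at 5.17 ± 0.17, Mall at 4.50 ± 0.16 and Mep1b at 4.42 ± 0.19 (camera adjusted p = 1.04e-19, and 0.0715 with an estimated correlation). Fatty acid oxidation had 14 higher and 1 lower of 19, with Cpt1a at 1.49 ± 0.14, Acadm at 1.46 ± 0.15 and Acadvl at 1.30 ± 0.18 (camera adjusted p = 1.03e-04, and 0.105 with an estimated correlation). Antimicrobial genes were 14 higher and 3 lower of 19, with Saa1 at 4.79 ± 0.10, Sprr2a3 at 4.21 ± 0.20, Gsdmc4 at 3.92 ± 0.14 and the pentraxin gene Mptx1 at -4.05 ± 0.15 (camera adjusted p = 1.84e-10, and 0.0599 with an estimated correlation). Saa1, Sprr2a3 and Gsdmc4 have near-identical neighbours. All 18 MHC class II and interferon genes were higher, with Ifit1 at 5.10 ± 0.34, Irf7 at 3.13 ± 0.17, Isg15 at 2.81 ± 0.18 and H2-Aa at 2.00 ± 0.09 (camera adjusted p = 5.65e-15, and 0.0520 with an estimated correlation). Absorptive transcription factors were 10 higher and 2 lower of 15, with Nr1h4, the bile acid receptor, at 1.98 ± 0.18 and the vitamin D receptor Vdr at 1.78 ± 0.13 (camera adjusted p = 6.02e-05, and 0.144 with an estimated correlation). Mitochondrially encoded genes were 12 higher of 13, with mt-Co3 at 1.36 ± 0.09 (camera adjusted p = 1.45e-20, and 0.0586 with an estimated correlation).

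Secretory, proliferative and crypt-base genes were lower in colonocyte-like cells. Of 29 secretory pathway genes 28 were lower, with Kdelr3, Creb3l4 (-4.25 ± 0.42), Pdia5 (-4.15 ± 0.25) and the stress sensor gene Ern2 (-3.62 ± 0.20) (camera adjusted p = 9.35e-20, and 0.0520 with an estimated correlation). Mucin glycosylation and secretion genes were 15 lower and 3 higher of 21, with Sytl2 at -3.52 ± 0.40 and Klk1 at -2.89 ± 0.16 (camera adjusted p = 3.64e-05, and 0.144 with an estimated correlation). Secretory and tuft transcription factors were 7 lower and 1 higher of 9, with Atoh1 at -3.94 ± 0.23 and Foxa2 at -3.61 ± 0.28 (camera adjusted p = 6.68e-04, and 0.144 with an estimated correlation). DNA replication had 14 lower and 2 higher of 20, with Dut at -3.29 ± 0.30 and Mcm5 at -3.11 ± 0.32 (camera adjusted p = 4.25e-05, and 0.0520 with an estimated correlation). Mitosis had 16 lower and 1 higher of 19, with Plk1 at -3.41 ± 0.39 (camera adjusted p = 1.65e-05, and 0.0783 with an estimated correlation). Wnt target genes had 9 lower and 1 higher of 17, with Myc at -3.15 ± 0.31 and Lrig1 at -2.75 ± 0.33 (camera adjusted p = 2.09e-03, and 0.116 with an estimated correlation). Ribosome biogenesis was lower in 17 of 18, with Nhp2 at -3.19 ± 0.25 and Gnl3 at -3.06 ± 0.38 (camera adjusted p = 6.77e-09, and 0.0339 with an estimated correlation). The other lists had no camera call, with 5 higher and 5 lower of 21 dissociation genes, 2 and 3 of 10 taste genes, 6 and 4 of 20 immune-type genes, 3 and 3 of 16 neuroendocrine genes, 2 and 0 of 9 enteroendocrine factors, 2 and 3 of 11 Notch genes and 7 and 3 of 12 reference genes. The reference genes Actb (1.72 ± 0.09) and Gapdh (1.19 ± 0.10) were higher and Eef1a1 (-1.26 ± 0.11) lower. Adjusted over the list alone, 14 brush border genes were higher and 1 lower, 29 secretory pathway, 16 replication and 18 mitosis genes were lower, and dissociation genes were 6 higher and 6 lower, while the other counts were the same. At resolution 0.5 the camera calls of DNA replication and mitosis were lost.

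**Figure D3:**
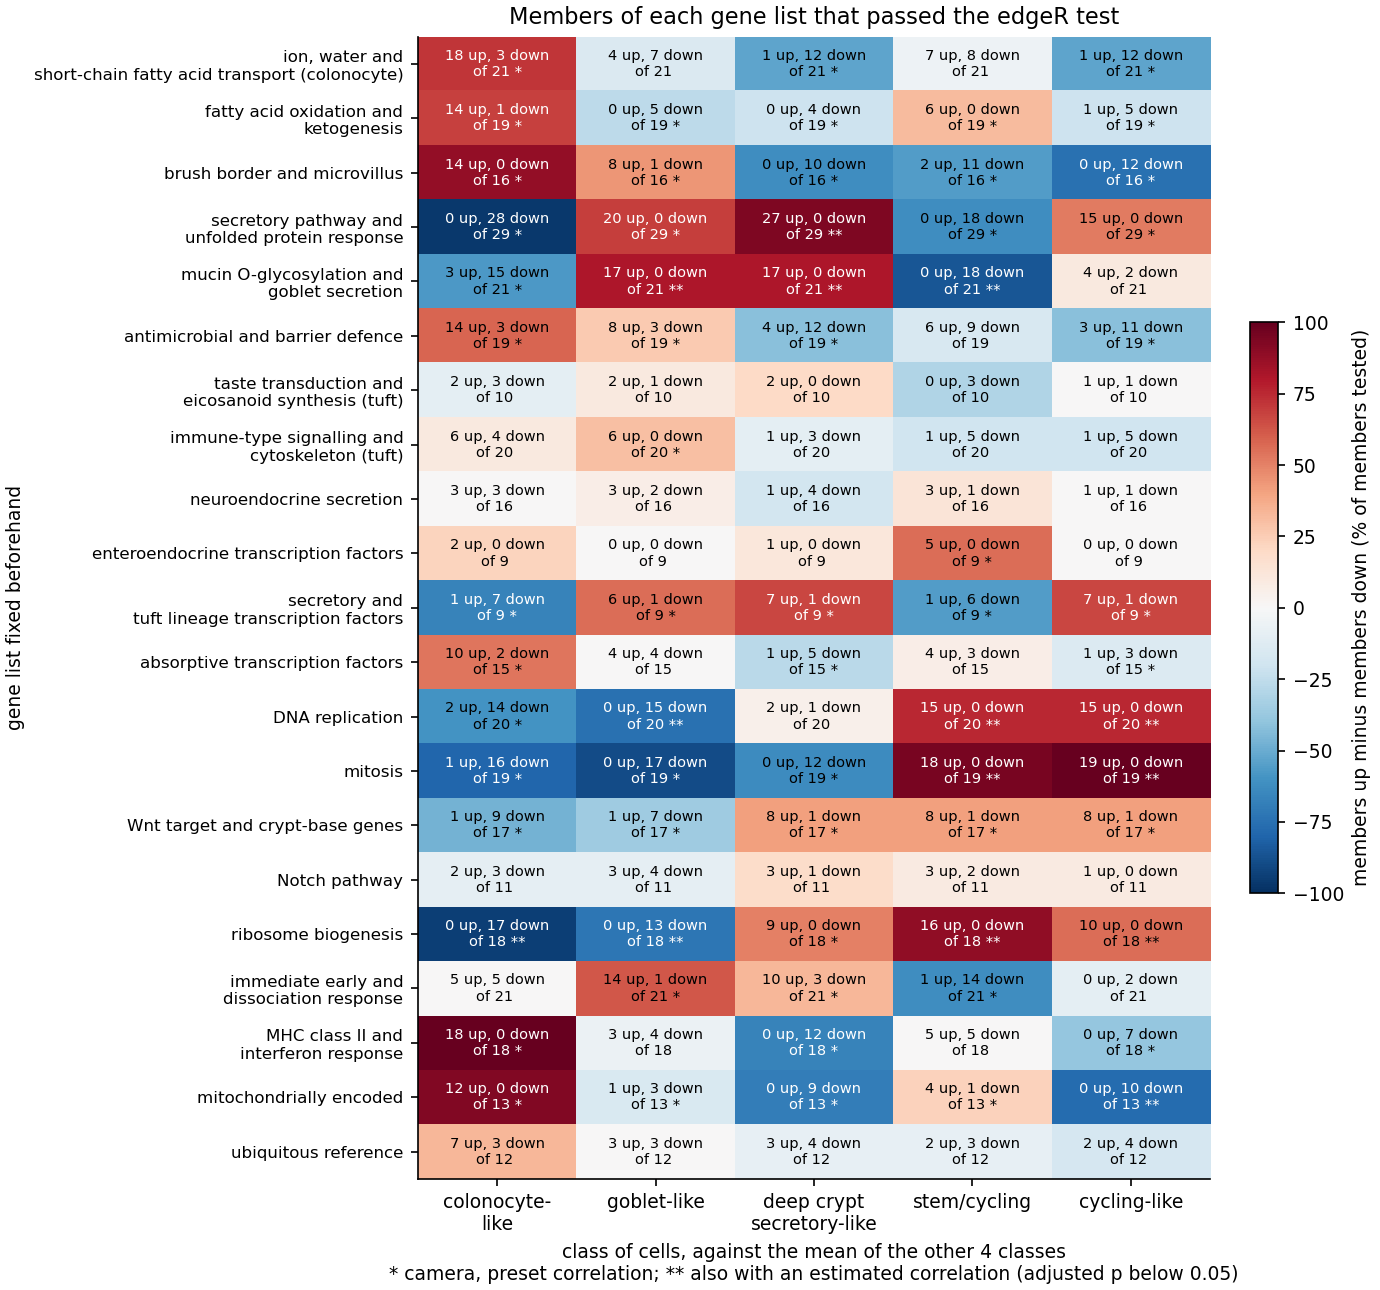
Members of the 21 gene lists higher and lower in each class. Of 21 transport genes 18 were higher in colonocyte-like cells, and of 29 secretory pathway genes 27 were higher in deep crypt secretory-like cells.

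In goblet-like cells the trypsin inhibitor gene Spink1 lay 6.18 ± 0.10 above the mean of the other classes on the log2 scale, Ceacam19 5.61 ± 0.18, Peli3 5.31 ± 0.23, Zfp644 5.25 ± 0.12 and the calpain gene Capn9 4.87 ± 0.18. Pooled ratios were 74.0 for Olfr448 (42.4 to 141), 55.7 for the galactosyltransferase gene B4galt2 (29.4 to 119) and 15.9 for Ahnak2 (11.1 to 23.2). C19orf25 (6.19 ± 0.16) and Cyp4x1os (5.76 ± 0.27) were also high, the former under a human-style symbol and the latter named as an antisense gene, and Olfr448 belongs to a family of similar genes, so that the source of their reads is uncertain. Ifitm3 lay at -5.07 ± 0.42, and Trmt61a was at least 4.66-fold lower than in the other classes pooled, a call lost with sums thinned to equal depth. In edgeR's quasi-likelihood test 1732 genes differed, 1037 higher and 695 lower, and 1012 by at least 2-fold. Over the alternatives the count was lowest, at 868, without the doublet filter. Ceacam19 had an adjusted p = 3.35e-211 and Peli3 an adjusted p = 9.35e-115 in the test with 1732 calls (edgeR, Benjamini-Hochberg). Against all other epithelial cells summed, 47.9% of the calls were higher and not 59.9%.

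Mucin glycosylation and secretion genes were higher in 17 of 21, with Capn9, Bcas1 (4.30 ± 0.12), the small GTPase gene Rab27a (4.17 ± 0.17) and Sytl2 (3.84 ± 0.20) (camera adjusted p = 7.21e-30, and 0.0292 with an estimated correlation). The secretory pathway was higher in 20 of 29, with Ern2 at 1.80 ± 0.13 and the chaperone gene Hspa5 at 1.01 ± 0.10 (camera adjusted p = 5.32e-12, and 0.0520 with an estimated correlation). Secretory and tuft transcription factors were 6 higher and 1 lower of 9, with Atoh1 at 2.16 ± 0.15, Gfi1 at 2.11 ± 0.24 and Spdef at 2.10 ± 0.20 (camera adjusted p = 3.35e-08, and 0.0586 with an estimated correlation). Dissociation genes were 14 higher and 1 lower of 21, with Dusp1 at 1.67 ± 0.15, Fosb at 1.63 ± 0.18 and Klf6 at 1.47 ± 0.13 (camera adjusted p = 7.20e-08, and 0.0586 with an estimated correlation). Immune-type genes were higher in 6 of 20, with Krt18 at 1.90 ± 0.11 and Il4ra at 1.52 ± 0.20 (camera adjusted p = 0.00403, and 0.149 with an estimated correlation). Brush border genes were 8 higher and 1 lower of 16, with Cdhr5 at 1.07 ± 0.13 and Lgals4 at 0.96 ± 0.10 (camera adjusted p = 0.00213, and 0.326 with an estimated correlation). Antimicrobial genes were 8 higher and 3 lower of 19, with a pooled ratio of 11.1 for Ang4 (6.91 to 18.2), at 41.7 CPM in replicate 1 and 7.97 CPM in replicate 2, and with Reg3b, a gene with a close paralog, at -3.28 ± 0.25 (camera adjusted p = 1.67e-04, and 0.0947 with an estimated correlation). Colonocyte-like cells hold far higher levels of many brush border and antimicrobial genes, and against all other cells summed the counts became 1 higher and 7 lower for brush border, 3 and 11 for antimicrobial, 3 and 16 for transport, 0 and 9 for mitochondrially encoded and 3 and 2 for immune-type genes.

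Goblet-like cells had lower levels of proliferation genes. DNA replication was lower in 15 of 20, with Mcm6 at -2.94 ± 0.33 (camera adjusted p = 4.74e-08, and 0.0333 with an estimated correlation). Mitosis was lower in 17 of 19, with Ccna2 at -3.27 ± 0.34 (camera adjusted p = 6.60e-11, and 0.0520 with an estimated correlation). Ribosome biogenesis was lower in 13 of 18, with Nolc1 at -1.61 ± 0.32 (camera adjusted p = 2.45e-07, and 0.0363 with an estimated correlation). Wnt target genes were 7 lower and 1 higher of 17, with Cd44 at -3.23 ± 0.41, Aqp4 at -2.01 ± 0.17 and Tnfrsf19 at 2.52 ± 0.41 (camera adjusted p = 0.00299, and 0.146 with an estimated correlation). Fatty acid oxidation was lower in 5 of 19, with Hadh at -1.11 ± 0.16 (camera adjusted p = 0.0105, and 0.203 with an estimated correlation). Mitochondrially encoded genes were 3 lower and 1 higher of 13 (camera adjusted p = 0.00224, and 0.266 with an estimated correlation). Transport had no camera call, with 4 higher, among them Scnn1b (4.13 ± 0.45) and the channel gene Best2 (3.51 ± 0.17), and 7 lower. Absorptive factors had no camera call either, with 4 higher, among them Id3 (2.61 ± 0.13) and Id1 (2.34 ± 0.11), and 4 lower, among them Vdr (-1.34 ± 0.19). The counts were 2 higher and 1 lower for taste genes, with the receptor gene Il13ra1 at 2.41 ± 0.12, 3 and 2 for neuroendocrine genes, 0 and 0 for enteroendocrine factors, 3 and 4 for Notch genes, 3 and 4 for MHC and interferon genes, with Gbp2 at 2.06 ± 0.14 and H2-Eb1 at -1.43 ± 0.13, and 3 and 3 for reference genes. Adjusted over the list alone, 21 secretory pathway genes were higher, dissociation genes were 15 higher and 2 lower, and the lower counts became 8 for transport, 6 for fatty acid oxidation, 16 for replication, 16 for ribosome biogenesis, 5 for mitochondrially encoded, 2 for taste and 5 for reference genes, while the other counts were the same. Without the doublet filter the calls of Ccna2, Nolc1, Cdhr5 and Lgals4 were lost. At resolution 0.5 the calls of Nolc1 and Cdhr5 and the camera calls of antimicrobial, Wnt, mitosis and ribosome biogenesis genes were lost, and that of brush border genes turned in direction. Without a replicate block the camera call of mitochondrially encoded genes was lost here and in stem/cycling cells. Cdhr5 turned to -0.26 against all other cells summed.

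In deep crypt secretory-like cells A4gnt, a glycosyltransferase gene, lay 4.05 ± 0.33 above the mean of the other classes on the log2 scale, Slc12a8 3.41 ± 0.16, the secreted phospholipase gene Pla2g2a 3.37 ± 0.17, the resistin-like gene Retnlb 3.24 ± 0.13, Creb3l4 3.22 ± 0.21, Spdef 3.19 ± 0.18, the matrilysin gene Mmp7 3.17 ± 0.37 and Plpp1 3.14 ± 0.17. Slc9a2 lay at -2.79 ± 0.34 and Nos2 at -2.78 ± 0.39. The ratio for Sprr2b, which has near-identical neighbours, was 0.0269 (0.00324 to 0.0980). In edgeR's quasi-likelihood test 1388 genes differed, 878 higher and 510 lower, and 651 by at least 2-fold. Over the alternatives the count went from 678 without a replicate block to 2635 without the doublet filter. Retnlb had an adjusted p = 8.53e-143 and Mptx1 (3.03 ± 0.10) an adjusted p = 1.93e-212 in the test with 1388 calls (edgeR, Benjamini-Hochberg). Against all other epithelial cells summed, 48.8% of the calls were higher and not 63.3%.

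Of 29 secretory pathway genes 27 were higher in deep crypt secretory-like cells, with Kdelr3 at 2.88 ± 0.22 and Pdia5 at 2.39 ± 0.15 (camera adjusted p = 1.18e-35, and 0.0292 with an estimated correlation). Mucin glycosylation and secretion was higher in 17 of 21, with Klk1 at 2.52 ± 0.11 (camera adjusted p = 2.27e-19, and 0.0410 with an estimated correlation), and 12 higher with 5 lower against all other cells summed. Secretory and tuft transcription factors were 7 higher and 1 lower of 9, with Atoh1 at 2.56 ± 0.14, Gfi1 at 1.93 ± 0.24 and Foxa3 at 1.58 ± 0.17 (camera adjusted p = 2.81e-08, and 0.0586 with an estimated correlation). Wnt target and crypt-base genes were 8 higher and 1 lower of 17, with Cd24a at 1.98 ± 0.11, Sox9 at 1.65 ± 0.15, Myc at 1.11 ± 0.22 and Aqp4 at -2.18 ± 0.17 (camera adjusted p = 3.70e-04, and 0.0971 with an estimated correlation). Ribosome biogenesis was higher in 9 of 18, with Gnl3 at 1.25 ± 0.27 (camera adjusted p = 5.38e-05, and 0.0732 with an estimated correlation). Dissociation genes were 10 higher and 3 lower of 21, with Fosb at 2.02 ± 0.17, Egr1 at 1.65 ± 0.14 and Jun at 1.30 ± 0.11 (camera adjusted p = 6.89e-07, and 0.0971 with an estimated correlation).

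Lists of absorptive, mitosis, and MHC class II and interferon genes leaned lower in deep crypt secretory-like cells, with part of their members called. Transport was 12 lower and 1 higher of 21, with Slc9a2, Atp12a at -2.41 ± 0.34 and Best2 at 2.58 ± 0.18 (camera adjusted p = 1.31e-09, and 0.0998 with an estimated correlation). Brush border was lower in 10 of 16, with Pls1 at -0.99 ± 0.13 (camera adjusted p = 8.44e-09, and 0.144 with an estimated correlation). Fatty acid oxidation was lower in 4 of 19 (camera adjusted p = 0.00722, and 0.185 with an estimated correlation). Antimicrobial genes were 12 lower, with Nos2, and 4 higher, with Pla2g2a, Retnlb and Mptx1, of 19 (camera adjusted p = 0.00208, and 0.170 with an estimated correlation). Absorptive factors were 5 lower and 1 higher of 15, with Id1 at -1.55 ± 0.15, Vdr at -1.05 ± 0.18 and Hnf4a at -1.01 ± 0.15 (camera adjusted p = 0.00235, and 0.216 with an estimated correlation). Mitosis was lower in 12 of 19, with Hmmr at -2.05 ± 0.45 and Tpx2 at -1.71 ± 0.33 (camera adjusted p = 4.85e-08, and 0.0520 with an estimated correlation). MHC and interferon genes were lower in 12 of 18, with Irf7 at -1.46 ± 0.29 and H2-Aa at -0.89 ± 0.12 (camera adjusted p = 5.74e-09, and 0.0797 with an estimated correlation). Mitochondrially encoded genes were lower in 9 of 13 (camera adjusted p = 2.30e-20, and 0.0586 with an estimated correlation). No camera call was made for taste genes, with 2 higher, among them Pde2a at 2.83 ± 0.17, and 0 lower, immune-type genes, with 1 and 3, among them Krt8 at -1.31 ± 0.11, neuroendocrine genes, with 1 and 4, enteroendocrine factors, with 1 and 0, DNA replication, with 2 and 1, Notch genes, with 3 and 1, among them the ligand gene Dll1 at 1.87 ± 0.36, and reference genes, with 3 and 4. Adjusted over the list alone, the higher counts became 28 for secretory pathway, 18 for mucin, 10 for Wnt target, 11 for ribosome biogenesis, 11 for dissociation, 3 for neuroendocrine and 2 for absorptive factor genes. The lower counts became 15 for transport, 5 for fatty acid oxidation, 12 for brush border, 14 for mitosis, 14 for MHC and interferon, 10 for mitochondrially encoded and 2 for Notch genes, while the other counts were the same. At resolution 0.5 and without the doublet filter the stem/cycling and cycling-like classes were lost from the fit, Tpx2 turned to 0.049 and 0.30, and the call of Hmmr was lost. At resolution 0.5 the camera call of dissociation genes was lost and that of mitosis genes turned in direction, and with sums thinned to equal depth the calls of Sprr2b and Dll1 were lost.

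In stem/cycling cells Zbed3 lay 3.77 ± 0.31 above the mean of the other classes on the log2 scale, Ifitm3 3.71 ± 0.18, Reg3b 3.61 ± 0.13, the NADPH oxidase gene Nox1 3.43 ± 0.19, Sox4 3.35 ± 0.21, Hmgn1 3.22 ± 0.17 and the serine synthesis gene Phgdh 2.97 ± 0.34. Mptx1 lay at -4.16 ± 0.16 and Klk1 at -3.41 ± 0.18, and C4orf17, under a human-style symbol, was at least 4.73-fold lower than in the other classes pooled. In edgeR's quasi-likelihood test 1753 genes differed, 890 higher and 863 lower, and 954 by at least 2-fold. With at least 2000 UMIs per barcode, chosen after seeing the data, 530 were higher and 679 lower, and with DESeq2 515 and 583. Without a replicate block 1032 genes differed. Ifitm3 had an adjusted p = 2.23e-89 and Reg3b an adjusted p = 4.40e-161 in the test with 1753 calls (edgeR, Benjamini-Hochberg). Reg3b has a close paralog in Reg3g.

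Mitosis genes were higher in 18 of 19 in stem/cycling cells, with Ccnb2 at 2.91 ± 0.21 and Plk1 at 2.51 ± 0.24 (camera adjusted p = 8.34e-24, and 0.0292 with an estimated correlation). DNA replication was higher in 15 of 20, with Dut at 2.02 ± 0.20 and Mcm5 at 2.02 ± 0.22 (camera adjusted p = 6.11e-12, and 0.0292 with an estimated correlation). Ribosome biogenesis was higher in 16 of 18, with Nhp2 at 1.75 ± 0.18 and Npm1 at 1.57 ± 0.12 (camera adjusted p = 2.00e-15, and 0.0292 with an estimated correlation). Wnt target genes were 8 higher and 1 lower of 17, with Cd44 at 2.97 ± 0.21, Aqp4 at 2.24 ± 0.12, Ephb3 at 1.93 ± 0.27 and Myc at 1.59 ± 0.22 (camera adjusted p = 2.05e-06, and 0.0534 with an estimated correlation). Fatty acid oxidation was higher in 6 of 19, with Hadh at 0.93 ± 0.13 (camera adjusted p = 0.00722, and 0.140 with an estimated correlation). Enteroendocrine transcription factors were higher in 5 of 9, with Insm1 at 3.61 ± 0.45, Neurog3 at 3.15 ± 0.56 and St18 at 1.90 ± 0.35 (camera adjusted p = 0.00851, and 0.120 with an estimated correlation). Neurog3 stood at 14.5 CPM in replicate 1 and 29.4 CPM in replicate 2. With the other set of genes for clustering the calls of Insm1 and Neurog3 were lost and Neurog3 turned to -1.60, and with DESeq2 the call of Neurog3 was lost. Mitochondrially encoded genes were 4 higher and 1 lower of 13 (camera adjusted p = 1.55e-04, and 0.191 with an estimated correlation).

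Mucin, secretory pathway, brush border and dissociation genes were lower in stem/cycling cells. Mucin glycosylation and secretion was lower in 18 of 21, with Rab27a at -3.21 ± 0.37 and Gcnt3 at -3.12 ± 0.22 (camera adjusted p = 1.10e-21, and 0.0292 with an estimated correlation). The secretory pathway was lower in 18 of 29, with Dnajc10 at -1.59 ± 0.17 (camera adjusted p = 1.34e-10, and 0.0520 with an estimated correlation). Secretory and tuft factors were 6 lower and 1 higher of 9, with Spdef at -2.73 ± 0.36, Atoh1 at -2.71 ± 0.24 and Sox4 higher (camera adjusted p = 0.00147, and 0.168 with an estimated correlation). Brush border genes were 11 lower and 2 higher of 16, with Cdhr5 at -1.47 ± 0.16 and Lgals4 at -1.21 ± 0.12 (camera adjusted p = 6.06e-06, and 0.175 with an estimated correlation). Dissociation genes were 14 lower and 1 higher of 21, with Dusp1 at -2.62 ± 0.24, Fos at -2.25 ± 0.15 and Hsph1 at 1.89 ± 0.22 (camera adjusted p = 1.65e-11, and 0.0520 with an estimated correlation). Without a camera call were antimicrobial genes, with 6 higher and 9 lower, among them Pla2g2a at -3.39 ± 0.36, transport, with 7 higher, among them Cftr at 2.66 ± 0.21 and Slc5a8 at 2.12 ± 0.14, and 8 lower, and Notch genes, with 3 higher, among them Notch1 at 2.11 ± 0.28 and Nrarp at 1.84 ± 0.26, and 2 lower. The counts were 0 higher and 3 lower for taste genes, 1 and 5 for immune-type genes, 3 and 1 for neuroendocrine genes, 4 and 3 for absorptive factors, with Nr3c2 at -1.55 ± 0.23, 5 and 5 for MHC and interferon genes, with H2-Eb1 at 0.99 ± 0.11 and Gbp2 at -2.89 ± 0.23, and 2 and 3 for reference genes. Adjusted over the list alone, the counts became 16 higher for replication, 19 for mitosis, 17 for ribosome biogenesis and 3 for brush border, 9 higher and 2 lower for Wnt target, 1 and 19 for secretory pathway, 1 and 16 for dissociation, 7 and 9 for transport, 6 and 11 for antimicrobial, 1 and 3 for taste, 5 and 4 for absorptive factor and 5 and 3 for Notch genes, while the other counts were the same. Against all other cells summed, transport was 2 higher and 14 lower.

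Cycling-like cells were led by mitotic genes. The kinase gene Pbk lay 4.03 ± 0.26 above the mean of the other classes on the log2 scale, Cdc20 3.91 ± 0.31, the kinase genes Aurka 3.88 ± 0.30 and Aurkb 3.49 ± 0.32, Nusap1 3.80 ± 0.28, Ccna2 3.56 ± 0.19 and Fam83d 3.44 ± 0.33. Hist1h2ap (4.09 ± 0.27) is one of many similar histone genes. Relative to the other classes pooled, where colonocyte-like cells weigh most, Mep1a was at least 22.3-fold and Cmbl at least 8.04-fold lower. Id3 lay at -2.96 ± 0.26. In edgeR's quasi-likelihood test 1176 genes differed, 664 higher and 512 lower, and 733 by at least 2-fold. Without a replicate block 688 differed. Pbk had an adjusted p = 3.57e-49 and Ccna2 an adjusted p = 3.16e-72 in the test with 1176 calls (edgeR, Benjamini-Hochberg). Against all other epithelial cells summed, 42.1% of the calls were higher and not 56.5%.

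All 19 mitosis genes were higher in cycling-like cells (camera adjusted p = 2.37e-53, and 0.0197 with an estimated correlation). DNA replication was higher in 15 of 20, with Rrm2 at 2.92 ± 0.27 and Mcm4 at 2.53 ± 0.30 (camera adjusted p = 1.10e-21, and 0.0221 with an estimated correlation). Ribosome biogenesis was higher in 10 of 18, with Gnl3 at 1.57 ± 0.35 and Nhp2 at 1.45 ± 0.22 (camera adjusted p = 6.62e-11, and 0.0292 with an estimated correlation). The cycling-like cells also carried secretory genes. Their cluster had the highest median doublet score of the named epithelial classes tested, 0.56. Its median depth of 9300.5 UMIs was the highest of these classes in replicate 2, while in replicate 1 it was 5215 UMIs, below goblet-like (5342), deep crypt secretory-like (5313) and stem/cycling cells (5897). Barcodes of mixed cells are not ruled out as a source. Their cluster held Reg4 at 3614 CPM in replicate 1 and 4034 CPM in replicate 2. The secretory pathway was higher in 15 of 29, with Pdia5 at 1.67 ± 0.19 and Creb3l1 at 1.56 ± 0.13 (camera adjusted p = 1.42e-09, and 0.0880 with an estimated correlation). Secretory and tuft factors were 7 higher and 1 lower of 9, with Sox4 at 2.02 ± 0.29, Atoh1 at 1.93 ± 0.17 and Klf4 at -1.80 ± 0.17 (camera adjusted p = 3.58e-05, and 0.108 with an estimated correlation). Wnt target genes were 8 higher and 1 lower of 17, with Cd44 at 1.79 ± 0.30 and Lrig1 at 1.5 ± 0.31 (camera adjusted p = 0.00221, and 0.147 with an estimated correlation). With at least 2000 UMIs per barcode, an alternative chosen after seeing the data, the camera calls of fatty acid oxidation and the secretory pathway were lost, and without a replicate block the call of the absorptive factor gene Klf5.

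**Figure D4:**
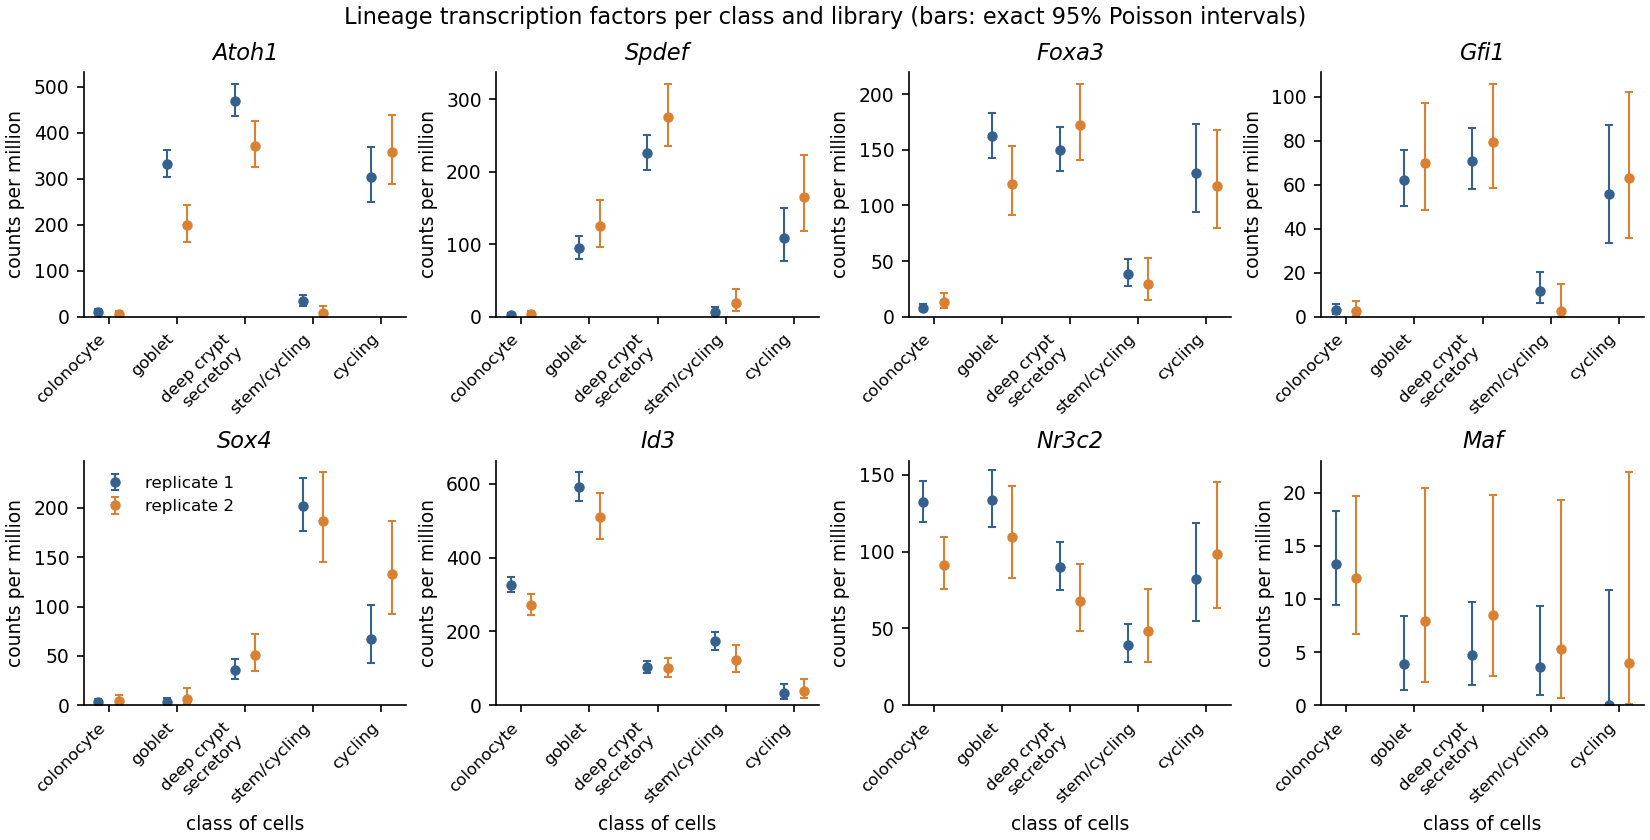
Levels of lineage transcription factors per class and library. The log2 fold change of Atoh1 was 2.16 in goblet-like, 2.56 in deep crypt secretory-like and 1.93 in cycling-like cells.

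Lists of absorptive genes leaned lower in cycling-like cells, with part of their members called. Brush border was lower in 12 of 16, with Mep1a and Cdhr2 at -2.22 ± 0.32 (camera adjusted p = 3.11e-10, and 0.125 with an estimated correlation). Transport was 12 lower and 1 higher of 21, with Slc6a14 at -2.44 ± 0.36 (camera adjusted p = 2.08e-06, and 0.144 with an estimated correlation). Fatty acid oxidation was 5 lower and 1 higher of 19, with Acadm at -1.49 ± 0.28 (camera adjusted p = 0.00270, and 0.157 with an estimated correlation). Antimicrobial genes were 11 lower and 3 higher of 19, with Saa1 at -2.77 ± 0.18 and Lypd8 at -2.42 ± 0.13 (camera adjusted p = 1.63e-05, and 0.125 with an estimated correlation). Absorptive factors were 3 lower and 1 higher of 15, with Id3, Id1 at -2.18 ± 0.20 and Klf5 at 0.58 ± 0.14 (camera adjusted p = 0.00379, and 0.220 with an estimated correlation). MHC and interferon genes were lower in 7 of 18, with H2-Aa at -0.86 ± 0.12 (camera adjusted p = 8.83e-05, and 0.144 with an estimated correlation). Mitochondrially encoded genes were lower in 10 of 13, with mt-Nd3 at -0.92 ± 0.12 (camera adjusted p = 1.17e-23, and 0.0333 with an estimated correlation). No camera call was made for mucin genes, with 4 higher and 2 lower, and 1 and 7 against all other cells summed, taste genes, with 1 and 1, immune-type genes, with 1 and 5, among them Krt8 at -1.83 ± 0.12, neuroendocrine genes, with 1 and 1, enteroendocrine factors, with 0 and 0, Notch genes, with 1 and 0, the ligand gene Dll1 at 2.84 ± 0.43, dissociation genes, with 0 and 2, and reference genes, with 2 and 4. Adjusted over the list alone, the higher counts became 17 for secretory pathway, 16 for replication, 14 for ribosome biogenesis, 5 for mucin and 2 for taste genes, and the lower counts 14 for transport, 9 for fatty acid oxidation, 13 for brush border, 12 for antimicrobial, 12 for mitochondrially encoded, 1 for dissociation and 5 for reference genes, while the other counts were the same.

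Among genes higher in goblet-like than in colonocyte-like cells, Best2 (6.16 ± 0.28) and Tpsg1 (6.16 ± 0.27) had the largest fitted folds, with Olfr448 at 6.06 ± 0.39, B4galt2 at 5.99 ± 0.46 and Ttr at 5.97 ± 0.37. With no UMI in goblet-like cells, St8sia5 was at least 23.4-fold, Alpi at least 12.4-fold and Tinag at least 5.34-fold lower. In edgeR's quasi-likelihood test 1942 genes differed, 934 higher and 1008 lower in goblet-like cells, and 1364 by at least 2-fold. With sums thinned to equal depth 1015 differed. Best2 had an adjusted p = 5.61e-102 and Tpsg1 an adjusted p = 4.27e-111 in the test with 1942 calls (edgeR, Benjamini-Hochberg). Deep crypt secretory-like cells, in a comparison chosen after seeing the data, exceeded goblet-like cells in Ifitm3 (4.75 ± 0.48), A4gnt (4.10 ± 0.51) and Mmp7, with a pooled ratio of 35.3 (9.42 to 297). They lay below them in Olfr448 (-5.87 ± 0.42), Spink1 (-5.68 ± 0.16), Ceacam19 (-5.51 ± 0.27), C19orf25 (-5.48 ± 0.24) and B4galt2 (-5.40 ± 0.48). Of 1255 genes that differed 606 were higher and 649 lower, 820 by at least 2-fold, with an adjusted p = 4.25e-255 for Spink1 (edgeR quasi-likelihood test, Benjamini-Hochberg). Without a replicate block 613 differed.

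Tuft-like cells were too few for a test, with 9 cells in replicate 1 and 2 in replicate 2 and 23342 UMIs together. Relative to 1773 other epithelial cells, their pooled counts were 111 times higher for Dclk1 (77.6 to 155), 46.6 times for the channel gene Trpm5 (26.0 to 78.1) and 430 times for Sh2d6 (260 to 709), all of them markers that gave the cluster its name. Among readout genes the ratio was 255 for the lipoxygenase gene Alox5 (137 to 461), 170 for the phospholipase gene Plcg2 (87.1 to 316), 37.2 for the phosphatase gene Ptpn6 (21.6 to 60.2), 17.7 for Cd24a (14.7 to 21.2) and 9.04 for Espn (6.03 to 13.0). Intervals lay above 1 for 18 of 22 immune-type and 6 of 15 taste genes, for 4 of 21 neuroendocrine genes and 1 of 11 enteroendocrine factors, and for 0 of 12 reference genes, 4 of which lay below. Among 10 secretory and tuft factors 2 lay above and 2 below. Sox4 had a ratio of 17.4 (10.2 to 27.9) with 17 of its 18 UMIs in replicate 1, Pou2f3 a ratio of 25.3 (2.95 to 98.4) from 2 UMIs, Klf4 a ratio of 0.178 (0.0367 to 0.520), and Atoh1 had 0 UMIs with an upper bound of 0.902. Of 10 enteroendocrine markers 4 also lay above 1, with 11 UMIs of Pyy and 10 of Gcg in 1 cell of replicate 1. At least 3 enteroendocrine markers occurred in 3 cells of replicate 1 and 1 cell of replicate 2, and the planned comparisons of enteroendocrine-like and tuft-like cells could not be made.

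Over all genes tested, the folds of the 2 libraries taken alone had Spearman correlations of 0.755 for colonocyte-like, 0.507 for goblet-like, 0.458 for deep crypt secretory-like, 0.496 for stem/cycling and 0.36 for cycling-like cells. Over the 5 classes 66 of 105 list tests were called by camera with the preset correlation and 14 with an estimated correlation. The 14 were mitosis, DNA replication and ribosome biogenesis in stem/cycling and cycling-like cells, mucin genes in goblet-like, deep crypt secretory-like and stem/cycling cells, the secretory pathway in deep crypt secretory-like cells, DNA replication and ribosome biogenesis in goblet-like cells, ribosome biogenesis in colonocyte-like cells and mitochondrially encoded genes in cycling-like cells. Fry called 77 lists in a single direction and 101 in either direction. The signs of the median, the mean and the test differed for some lists without a camera call. These were neuroendocrine genes in every class, enteroendocrine factors in colonocyte-like, goblet-like and deep crypt secretory-like cells, dissociation genes in colonocyte-like and cycling-like cells, transport in goblet-like and stem/cycling cells, and reference genes in deep crypt secretory-like and stem/cycling cells. They also were taste, absorptive factor and Notch genes in goblet-like cells, immune-type and DNA replication genes in deep crypt secretory-like cells, and MHC and interferon genes in stem/cycling cells.

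Replicates 1 and 2 had similar levels across genes, with a Pearson correlation of 0.97 and a Spearman correlation of 0.967 of log levels over 16713 genes, which are not independent. Mitochondrially encoded genes held 5.71% of all UMIs in replicate 1 and 10.8% in replicate 2, and the share was higher in replicate 2 in every class. It ranged from 3.43% in goblet-like to 7.15% in colonocyte-like cells in replicate 1. In replicate 2 it ranged from 6.60% in deep crypt secretory-like to 12.6% in colonocyte-like cells. Piezo2, a mechanosensitive channel gene, stood at 78.0 CPM in replicate 1 and 332 CPM in replicate 2, Med18 at 22.1 and 90.9 CPM, Hdhd3 at 45.6 and 167 CPM, Armc2 at 14.0 and 57.4 CPM and Fibin at 15.4 and 54.4 CPM. Ccbl1 (22.3 and 15.8 CPM) and Dnajc9 (33.2 and 23.2 CPM) were lower in replicate 2. Of 8881 genes, 131 were higher and 12 lower in replicate 2 in every class with a mean ratio over the classes above 2-fold. The summed level of the dissociation list was 3125 CPM in replicate 1 and 3009 CPM in replicate 2. The enteroendocrine transcription factors, summed, stood at 49.4 and 105 CPM over the epithelial classes and at 98.0 and 275 CPM in stem/cycling cells. With 1 library on each side no test was made.

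**Figure D5:**
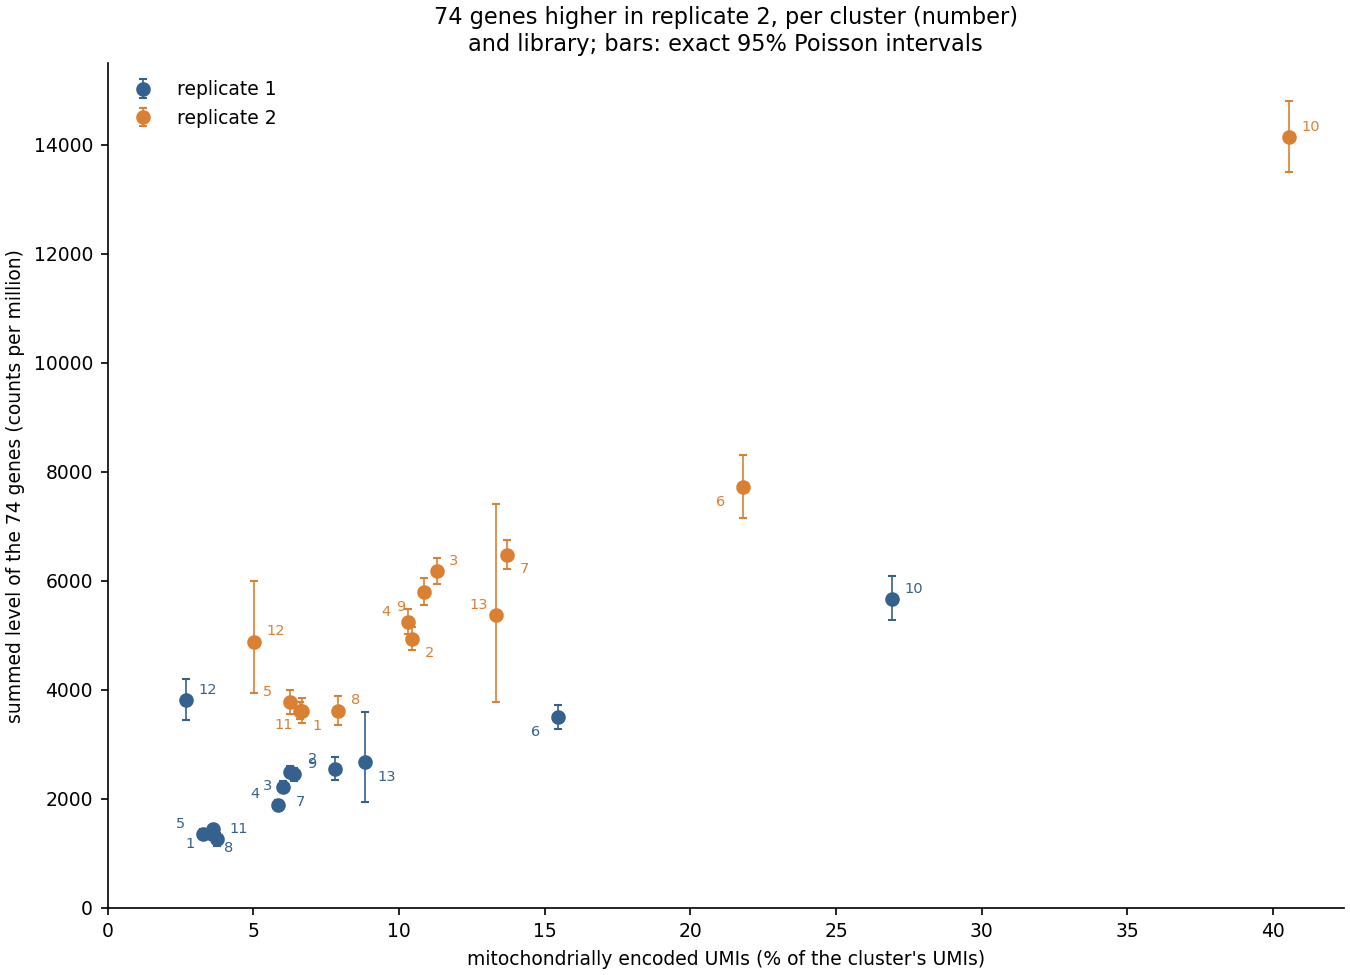
Summed level of 74 of the genes higher in replicate 2, per cluster and library, against the cluster's mitochondrially encoded share. In the cluster with the highest share it was 5672 CPM in replicate 1 and 14144 CPM in replicate 2.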

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

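All tests described here for the human-style symbols were chosen after the result was seen. The mouse tables hold 461 gene entries with symbols of the human form, a C, a number and orf, and 460 of them match human symbols or synonyms. They held 29946 UMIs, which is 0.239% of all UMIs. In the largest unnamed cluster they made up 0.362% of UMIs in replicate 1 and 0.370% in replicate 2. The human K562 cells themselves were not analysed here, and the tables used hold no human totals per barcode.

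A candidate explanation is that gene entries were sorted into mouse and human by the letter case of the symbol, because mouse symbols have lower-case letters and human symbols of this form are the only common ones that do. Of 25504 gene symbols, 0 lack a lower-case letter, as that explanation predicts, and an all-capital mouse symbol would have spoken against it. Free K562 RNA in equal amount in every droplet, as the only source, could not be decided. Human-named UMIs per barcode were 2.96 times higher in the deepest than in the shallowest named epithelial cluster (95% interval 2.75 to 3.19). Equal amounts predict a ratio near 1 only if every droplet is captured and read alike. Total depth differed between those clusters by 3.94 times, and a droplet read more fully would also yield more free RNA. The human-named share was 0.270% in the shallowest and 0.175% in the deepest cluster in replicate 1, and 0.286% and 0.257% in replicate 2.

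Mouse reads counted on human genes may be part of the signal. Of 133 human-named entries tested, 38 differed between the mouse epithelial classes, which is 28.6% (21.1% to 37.0%), against 4207 of 8049 other genes, or 52.3%. C19orf25, at a log2 fold change of 6.19 in goblet-like cells, is the largest of them. Most of the calls in colonocyte-like cells, a class that holds the shallow cluster, were higher. Free RNA may weigh more at low depth, so that those calls cannot tell mouse reads from free RNA. Free K562 RNA as part of the signal was not excluded, and the reads needed to decide the species of single molecules were not analysed here.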

How the results depend on the processing

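The minimum of 2000 UMIs per barcode, the other gene set for shares, the class without its shallow cluster and the comparison of deep crypt secretory-like with goblet-like cells were chosen after the data were seen, and the other alternatives before the data were examined. Over the alternatives with a test 5680 values of named genes kept their call, 352 lost it and 26 changed sign. Each library alone gave folds and no test, and its sign had chosen the named genes. Of list results 306 were kept, 63 lost and 2 reversed, and of gene counts 70 stayed within 1.5-fold and 22 moved. Shares were compared with the exact interval given above for the same class and library. Of these shares 69 lay inside that interval and 28 moved outside it. Relative log expression factors, 50 UMIs per gene, no low-count filter, at most 20% mitochondrially encoded UMIs, resolution 2, the other set of clustering genes and a minimum of 2000 UMIs left the total number of genes that differed within 1.5-fold in each comparison. The last of these took the stem/cycling genes called higher from 890 to 530, with 679 lower. The other set of clustering genes left mostly other genes to test, with a value for 269 of the 3336 colonocyte-like calls. Its totals therefore do not cover the same genes. The K562 alternatives could not be run.

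Fewer genes passed in 3 settings. With sums thinned to equal depth 1790 genes differed for colonocyte-like, 1011 for goblet-like, 746 for deep crypt secretory-like and 1111 for stem/cycling cells, 1015 between goblet-like and colonocyte-like cells and 659 between deep crypt secretory-like and goblet-like cells. With the DESeq2 Wald test the counts were 1065 for goblet-like, 797 for deep crypt secretory-like and 1098 for stem/cycling cells, and 1191 and 730 for the pairs. With no replicate block they were 1074 for goblet-like, 678 for deep crypt secretory-like, 1032 for stem/cycling and 688 for cycling-like cells, and 1230 and 613 for the pairs.

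Coarser clustering removed classes. At resolution 0.5 and without the doublet filter the stem/cycling and cycling-like cells were unnamed, so that 3 classes entered the fit and the reference of each contrast changed by construction. Goblet-like cells then had 949 and 868 calls, and deep crypt secretory-like cells 2370 and 2635. Against all other epithelial cells summed, deep crypt secretory-like cells had 2160. At resolution 0.5, 37 of 63 list tests were called by camera. Of these 63 tests 41 were called at resolution 1, and 32 were called in both with the same direction. With an estimated correlation 14 of 105 were called. At resolution 0.5 camera's direction turned for brush border genes in goblet-like cells (adjusted p = 0.174, and at most 0.326 over the alternatives) and for mitosis genes in deep crypt secretory-like cells (adjusted p = 0.136, the largest over the alternatives), so that neither was called.

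Genes that changed sign did so mostly at those settings. At resolution 0.5 Snap25 in colonocyte-like cells moved to 0.11, Cdhr2 in goblet-like cells to -0.00501, and in deep crypt secretory-like cells Gins2 to 0.37, Tpx2 to 0.049, Plk1 to 0.43 and Kif23 to 0.086. Without the doublet filter Snap25 moved to 0.24 in colonocyte-like and 0.43 in deep crypt secretory-like cells, Cdhr2 and mt-Co1 in goblet-like cells to -0.051 and -0.15, and in deep crypt secretory-like cells Gins2 to 0.57, Hmmr to 0.14, Tpx2 to 0.30, Plk1 to 0.69 and Kif23 to 0.26. Against all other cells summed, where colonocyte-like cells weigh most, goblet-like values were -0.68 for Cdhr2, -0.11 for mt-Co1, -0.48 for Atp12a, -0.26 for Cdhr5, -0.050 for Espn and -0.34 for Irf7, and Klk1 in cycling-like cells was -0.44. With the other set of clustering genes Neurog3 in stem/cycling cells was -1.60. With a minimum of 2000 UMIs Agt in stem/cycling cells was 0.85, and Slc5a8 and Aqp4 in cycling-like cells were 0.0029 and 0.18. The cause of the last 4 was not tested.

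Shares moved with the clusters that kept a name. At resolution 0.5 colonocyte-like cells made up 24.4% of replicate 1 and 22.5% of replicate 2, and unnamed cells 37.3% and 51.7%. At resolution 2.0 deep crypt secretory-like cells made up 15.1% and unnamed cells 15.3% of replicate 1. With the other set of clustering genes colonocyte-like cells made up 25.6% and 20.3%, unnamed cells 19.99% and 39.1%, and stem/cycling cells 9.67% of replicate 2. With a minimum of 2000 UMIs goblet-like cells made up 22.5% and 14.1%, cycling-like cells 7.83% and 6.75%, unnamed cells 1.58% and 20.4%, deep crypt secretory-like cells 19.8% of replicate 1 and stem/cycling cells 11.1% of replicate 2. Unnamed cells were 9.65% and 29.5% with at most 20% mitochondrially encoded UMIs, and 29.5% and 44.3% without the doublet filter. Clustered alone, replicate 1 had 15.6% stem/cycling and 10.6% cycling-like cells, and replicate 2 had 24.2% colonocyte-like, 8.08% cycling-like and 40.3% unnamed cells. No cluster of replicate 2 alone took the stem/cycling or the tuft-like name. Between the settings that named them cycling-like cells ranged from 3.45% to 10.6% in replicate 1.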

Other observations

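The contrasts between clusters and the tests on the unnamed cluster and on the genes of replicate 2 were chosen after the result was seen. The 3 deeper colonocyte-like clusters were compared with one another by edgeR's quasi-likelihood test, in 1 setting only. The first, led by Fabp6, Clca4b and Cldn8, was higher than the other 2 in the proton pump gene Atp12a (3.0 ± 0.16 on the log2 scale), the calcium binding gene S100g (3.29 ± 0.37), the sodium pump regulator gene Fxyd4 (3.31 ± 0.35) and Slc37a2 (3.22 ± 0.22), and lower in Reg3b (-4.84 ± 0.22) and Reg3g (-3.82 ± 0.21), with 317 genes that differed. Apart from these 2 genes, 11 of 19 antimicrobial genes were higher, and 8 of 21 transport genes were higher and 0 lower. The second, led by Emp1, Aqp8, Cyp2c55 and Guca2a, was higher in Mal (3.44 ± 0.24), Clca4a (3.24 ± 0.24) and the mucin gene Muc4 (3.03 ± 0.27), with 11 of 16 brush border genes higher and 460 genes that differed. Its transport genes were 7 higher and 2 lower of 21, its antimicrobial genes 8 higher and 4 lower of 19, and 11 of 29 secretory pathway genes were lower. Immediate early and dissociation genes moved with these contrasts. Handling as the cause was not tested and is not excluded. Of 21 such genes 7 were higher in the second cluster, where mt-Co1 and mt-Co3 were also higher, and 7 were lower in the first. In the third cluster 3 were higher and 2 lower, and of 13 mitochondrially encoded genes mt-Co1, mt-Co2 and mt-Co3 were lower and 0 higher. The third, led by Gsdmc, Asphd2 and Car1, was higher in Reg3b (3.15 ± 0.16) and Sult1a1 (2.75 ± 0.23), and lower in Clca4a (-4.38 ± 0.34), Atp12a (-4.34 ± 0.22) and Slc15a1 (-3.93 ± 0.29). Of its 767 genes that differed 443 were lower, among them 10 of 16 brush border, 11 of 21 transport and 12 of 18 MHC and interferon genes. In it 2 transport genes, Car2 and Cftr, were higher. Its antimicrobial genes were 5 higher and 8 lower of 19, with Saa1 at -3.53 ± 0.16, and 6 of 19 fatty acid oxidation genes were higher.

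The 2 goblet-like clusters differed in 389 genes, 226 of them higher in the cluster led by Clca1, Fcgbp and Zg16. That cluster was higher in Ido1 (3.43 ± 0.23) and Slfn4 (2.96 ± 0.34), with 9 of 19 antimicrobial genes higher and 2 lower. Of 21 dissociation genes 1 was higher in it and 5 were lower, among them Fos and Ier2, so that handling is not excluded here either. Ang4 stood at 75.1 against 7.75 CPM in replicate 1 and at 9.72 against 5.17 CPM in replicate 2, so that replicate 1 decides its fold. The other cluster, led by Sval1, Scin and Slpi, was higher in Sox9 and Pla2g2a, which lay at -3.27 ± 0.55 and -2.56 ± 0.41, and in 6 of 18 ribosome biogenesis genes. Its deep crypt secretory score was 3.13 against 2.42, its median doublet score 0.54 against 0.3, and its median depth 6596 against 4292 UMIs. Barcodes of mixed cells are not ruled out here. Position along the crypt and along the colon was not measured, and no order between clusters was tested.

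The largest unnamed cluster held 8.66% of the cells of replicate 1 and 25.2% of replicate 2, with a median of 1646.5 UMIs. A candidate explanation is that its barcodes hold a mixture of free RNA from all epithelial classes. The markers of every class lay within 1 log2 unit of the pooled named epithelial cells, the largest median ratio being -0.54, as a mixture predicts. The cluster stayed unnamed because no marker of its best class led it, so that levels far above the pool were largely ruled out beforehand. The marker levels are therefore weak support. Its Spearman correlation with all other cells was 0.896 in replicate 1 and 0.910 in replicate 2, the highest of 13 clusters. Doublets would be deeper and score higher, whereas its depth and its median doublet score of 0.12 lay below the 4292 to 7532 UMIs and 0.3 to 0.56 of the deeper epithelial clusters. Cells of low quality would leave much the same trace as free RNA and were not excluded.

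The 131 genes higher in replicate 2 in every class, and over 2-fold on the mean of the classes, include Piezo2, Med18 and Fibin. The 74 of them open to the test stood at 1897 CPM in named epithelial cells of replicate 1 and 4955 CPM in replicate 2. Something that goes with the mitochondrially encoded share of a barcode may be part of the cause. Within replicate 1 their level in the cluster with the highest such share was 2.99 times that in named epithelial cells (2.78 to 3.22). Hdhd3, a gene higher in replicate 2, was among that cluster's leading genes, so that clustering may have gathered barcodes rich in such genes. That cluster is also shallow, and shallow T cell-like cells stood at 3809 CPM with a share of 2.69%, against 5.29% in named epithelial cells. In the largest unnamed cluster of replicate 1, whose barcodes had no part in choosing the genes, the level was 3256 CPM above the median share and 1719 CPM at or under it, at median depths of 1418 and 1249 UMIs. In that cluster replicate 2 barcodes with the lower share of 7.0% were set against replicate 1 barcodes with the higher share of 11.6%. The level in the former was 1.24 times that in the latter (1.10 to 1.41), at median depths of 2126.5 and 1418 UMIs. The share as the only cause predicts a ratio below 1. With 1 library on each side and unequal depths, whether the share is the only cause stays open. Both libraries come from 1 mouse and 1 sequencing run, so that no difference between animals is involved, and any difference in handling is not given in the sources used here.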
